A study of Homo sapiens with 9 samples.

How the data were processed

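RNA of MCF-7 cells was sequenced 2 days after transfection, with a lipid reagent, of siRNA against CtBP1 and CtBP2, siRNA against TRIM28 or control siRNA, in 3 biological replicates per group according to the labels. Per the submitters' processing notes, the authors checked reads with FastQC, aligned them to hg38 with Bowtie2 2.4.4 and counted them per gene with featureCounts 2.0.3. The authors deposited FPKM values, which scale the fragments of a gene by its length and by the size of the library. The annotation, the FPKM tool, any filter and the strandedness of the libraries are not given in the sources used here, nor are the siRNA sequences.

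The 58735 gene identifiers of the table were the same as those of GENCODE 29, which gave symbols, biotypes, coordinates on hg38 and summed exon lengths. Each deposited FPKM value times that exon length was a whole multiple of 1 step per library within a tolerance of 0.01, for 100% of values, so the reads behind the values could be recovered. Recovered totals ranged from 16683150 to 18911388 reads per library, and the divisor of the FPKM was the geometric mean of the totals times a median-ratio factor. A splice-unaware aligner such as Bowtie2 loses reads over exon junctions, so genes with many short exons can be undercounted. Reads shared between paralogs or pseudogenes can be assigned to the wrong gene, as for RPSA, HLA genes or the pair IFNL2 and IFNL3. So can reads of overlapping antisense genes, as for TGFB2, since the strandedness is not given. Values of such genes are uncertain.

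Values were taken as log2(FPKM + 0.5), which pulls fold changes of genes near or under 0.5 FPKM toward 0. The 14074 genes with a mean of at least 0.5 FPKM over the 9 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a trend). All 9 libraries entered 1 fit with 3 group means and 6 residual degrees of freedom, so a library of 1 group also bears on the spread used for the other comparisons. Tests were two-sided, p values were adjusted by the Benjamini-Hochberg method over the genes tested, and genes at an adjusted p under 0.05 were called, with no minimum fold change. A single comparison of 3 libraries with 3 has a smallest two-sided p of 0.1 in an exact permutation test. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

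Comparisons, tests, gene lists, most alternatives and the rule for named genes were set before the data were examined. The rule names the targets, and for each knockdown the 10 largest rises and 10 largest falls among called protein-coding genes with a mean of at least 1 FPKM whose 2 groups did not overlap. It also names up to 2 members per direction of each list among those called, 6 genes per direction called alike in both knockdowns, 3 per pattern called in opposite directions, and 5 per direction in the comparison of the knockdowns. Of the genes the rule takes, 1 is not reported here. Examples outside the rule are said to be chosen after their values were seen.

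Gene lists were tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over the 34 lists with at least 5 tested members, with an estimated correlation and with fry, which tests whether the genes of a list move on balance one way, beside it. There were 36 lists from background knowledge and 2 made by rule, all ZNF genes on chromosome 19 and all others. The lists covered CtBP and TRIM28 complexes and targets, interferon, NF-kB and p53 genes, the cell cycle and DNA repair, breast lineage, epithelial and mesenchymal genes, signalling, metabolism and stress, translation and mitochondria, and markers of cell types other than MCF-7. Fry found 17 lists with CtBP1/2 siRNA and 8 with TRIM28 siRNA past 0.05, in part other lists than camera. With CtBP1/2 siRNA, camera called oxidative phosphorylation and ribosomal protein genes but fry did not (fry adjusted p 0.239 and 0.399). With TRIM28 siRNA, fry did not call these (0.189 and 0.641), nor recombination (0.0599) or TRIM28 and HUSH genes (0.137), which camera called. The other lists that camera called passed fry as well. Notch and Wnt targets passed fry with TRIM28 siRNA (0.00226) but not camera.

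To look for effects of siRNA seeds, each 7-base word was tested for whether genes with it in the longest annotated 3′ UTR differed in log2 fold change from genes without it, after adjustment for UTR length, UTR GC content and mean expression, over 15863 words and 11311 genes. The lowest z was compared with the lowest of 100 runs with permuted genes. Genes without an annotated 3′ UTR were not searched. The words reported for genes that fell were those with the lowest z in these same fold changes. Their higher share among genes that fell follows in part from that choice. Such shares were not adjusted for UTR length.

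The overlap of the knockdowns was compared with independent lists and with 100 simulations of unchanged groups measured against the same controls. In data simulated from the library means and sizes, with 50 genes changed per fold, the CtBP1/2 comparison called 14% of genes changed 1.25-fold, 78% at 1.5-fold, 90% at 2-fold and 98% at 4-fold, with 5 false calls among 14074 genes. The TRIM28 comparison called 6%, 56%, 86% and 98%, with 3 false calls. All simulated libraries had the same dispersion of 0.005, with no noisier group and no library that stood apart, so these shares may be too high for the real data. The noise was the same for both comparisons, so the differences between their shares reflect the random draws only. Alternatives were pseudocounts of 0.1 and 1, no filter or a filter at 1 FPKM, quantile normalization, rescaling of each library to the same FPKM sum, median-ratio scaling, no variance trend, library quality weights, only the 2 groups compared, a replicate block, a minimum of 1.5-fold, voom on recovered reads, and each library left out. Removal of a GC and length trend and of genes with a 3′ UTR word were added after the data were seen.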

Results

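Transcript levels were measured by RNA sequencing in MCF-7 cells, an estrogen-responsive human breast cancer line of epithelial origin. The cells had received small interfering RNA (siRNA) against both CtBP1 and CtBP2, against TRIM28, or control siRNA, and RNA was taken 2 days later. Whether a single siRNA or a pool was used is not given. CtBP1 and CtBP2 are related NADH-binding corepressors that bring histone deacetylases and demethylases to promoters, and TRIM28 is a corepressor recruited by zinc finger proteins with a KRAB domain. Each of the 3 groups held 3 libraries that the labels call biological replicates. The libraries held between 16683150 and 18911388 reads recovered from the deposited FPKM values, and between 11956 and 12370 genes stood at 1 FPKM or more. Errors on FPKM values are SD with n = 3, and errors on log2 fold changes are the standard errors of a limma model with n = 3 per group. That model uses a spread per gene that the 3 groups share. Deviations of libraries from their group mean had an SD of 0.205 to 0.324 with TRIM28 siRNA, against 0.149 to 0.171 in the other groups. The errors on fold changes with TRIM28 siRNA can therefore be too small.

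The transcripts aimed at by the siRNAs were reduced in the libraries labelled for them. CTBP1 (ENSG00000159692, chromosome 4, 1211448 to 1249953, hg38) stood at 3.47 ± 0.21 FPKM with CtBP1/2 siRNA and at 11.4 ± 0.162 FPKM with control siRNA, or 30.4% of the control mean. CTBP2 (ENSG00000175029, chromosome 10, 124984317 to 125161170) stood at 4.57 ± 0.0993 FPKM against 19.5 ± 0.416 FPKM, or 23.4%. TRIM28 (ENSG00000130726, chromosome 19, 58544091 to 58550722) stood at 19.7 ± 2.98 FPKM with TRIM28 siRNA and at 77.0 ± 1.78 FPKM with control siRNA, or 25.6%. The adjusted p values were 8.05e-06 for CTBP1, 2.49e-06 for CTBP2 and 4.46e-05 for TRIM28. Neither knockdown changed the other target past the threshold. TRIM28 stood at 113% of control with CtBP1/2 siRNA (adjusted p 0.227), and with TRIM28 siRNA CTBP1 and CTBP2 stood at 94.0% and 96.7% (adjusted p 0.484 and 0.666). The TRIM28 values with CtBP1/2 siRNA (84.62 to 89.5 FPKM) did lie above those with control siRNA (75.2 to 78.77 FPKM). The test of that difference uses a spread that includes the values with TRIM28 siRNA (17.43 to 23.08 FPKM).

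**Figure D1:**
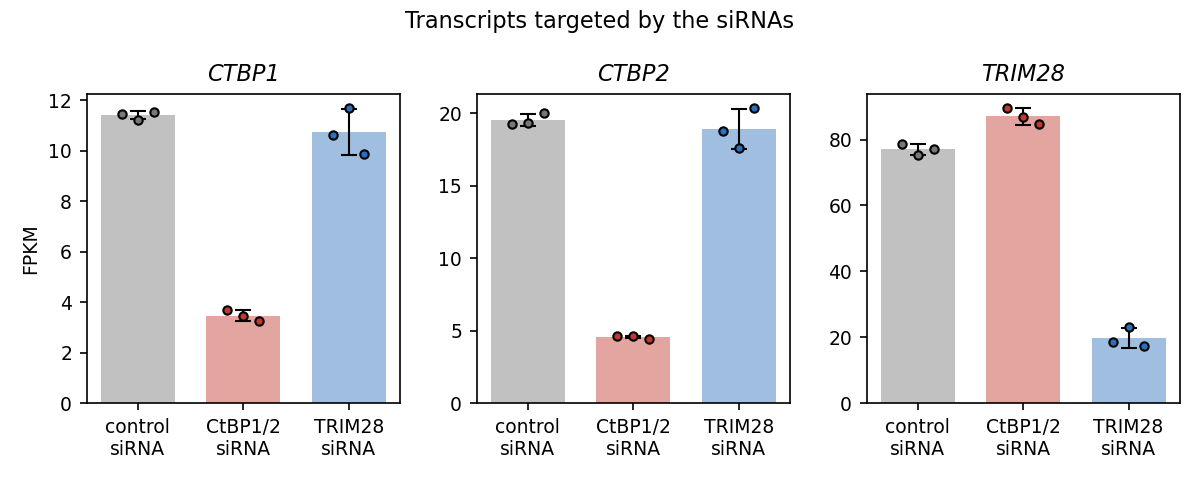
FPKM of CTBP1, CTBP2 and TRIM28 in the 3 siRNA groups, with bars at the mean, error bars of 1 SD and points for the 3 libraries of each group. CTBP1 and CTBP2 are lower in the 3 CtBP1/2 siRNA libraries than in the other 6, and TRIM28 is lower in the 3 TRIM28 siRNA libraries than in the other 6.

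The first principal component of the log2 values, with 36.7% of the variance, placed the CtBP1/2 siRNA libraries between -28.7 and -28.0 and the other 6 libraries between 6.77 and 31.5. Along the second, with 30.0%, TRIM28 siRNA replicate 2 stood at 42.9 while replicates 1 and 3 of that group stood at -8.75 and -3.32. Its correlation across genes with those replicates was 0.964 and 0.969, against 0.987 between them and 0.987 to 0.990 within the other groups. In replicate 2, all 72 ribosomal protein genes tested were higher than the mean of replicates 1 and 3, with a median difference of 0.70 on the log2 scale. Of 45 nuclear genes for oxidative phosphorylation subunits 44 were higher, with a median of 0.55, and 12 of 13 mitochondrially encoded genes were lower, with a median of -0.52. TRIM28 itself stood at 23.1 FPKM in that library.

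**Figure D2:**
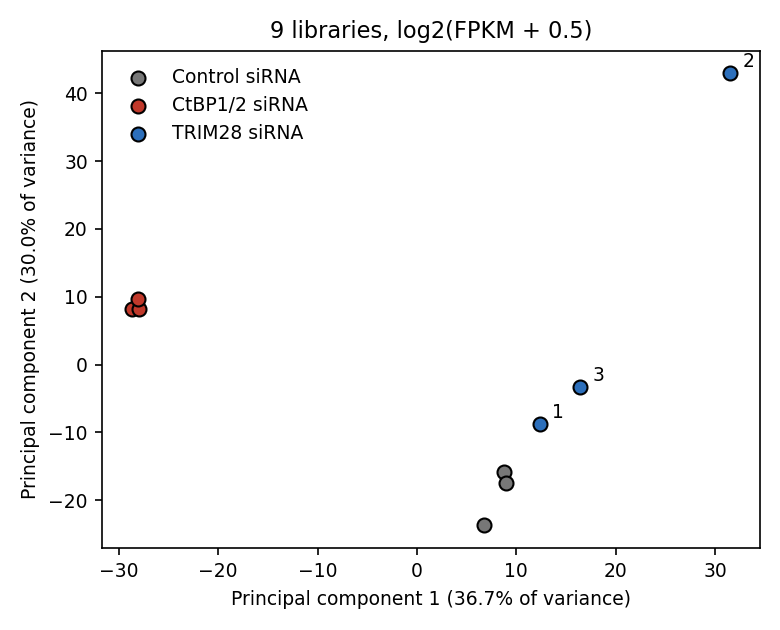
First 2 principal components of log2(FPKM + 0.5) in the 9 libraries, with 1 point per library coloured by siRNA group and the TRIM28 siRNA libraries numbered by replicate. TRIM28 siRNA replicate 2 lies at 42.9 on the second component, apart from its replicates at -8.75 and -3.32.

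The comparison of CtBP1/2 siRNA with control siRNA asks which transcripts change when both CtBP proteins are lowered. CDKN2B, an inhibitor of the cyclin D kinases, rose from 2.33 ± 0.157 to 11.4 ± 0.528 FPKM (log2 fold change 2.08 ± 0.11), and TGFB2, a TGF-beta ligand, from 11.5 ± 0.663 to 45.6 ± 1.10 FPKM (1.94 ± 0.17). OAS2, an antiviral synthetase activated by double-stranded RNA, fell from 163 ± 3.16 to 44.1 ± 0.551 FPKM. TUFM, the elongation factor of mitochondrial translation, fell from 127 ± 1.62 to 34.5 ± 0.146 FPKM, and P4HB, a protein disulfide isomerase of the endoplasmic reticulum, from 101 ± 3.59 to 29.6 ± 1.47 FPKM.

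In all, 3498 of 14074 genes tested (24.9%) changed at an adjusted p under 0.05, 1708 higher and 1790 lower. Of these, 1308 differed by at least 1.5-fold and 257 by at least 2-fold, 120 higher and 137 lower. Further large rises were those of BNIPL (1.85), the decoy TRAIL receptor gene TNFRSF10C (1.77), PGM2L1 (1.76), the mitochondrial ferredoxin reductase gene FDXR (1.68), TEX14 (1.66), TMEM40 (1.54) and GPNMB (1.52). Besides CTBP2 (-1.98), OAS2, TUFM and P4HB, the largest falls were those of RTP4 (-1.85), CD74 (-1.85), SLC15A3 (-1.85), PTP4A3 (-1.83), GBP4 (-1.77) and MX2 (-1.73). CD74 encodes the invariant chain of MHC class II. RTP4, GBP4 and MX2 are known as interferon-inducible genes.

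Interferon-stimulated genes fell as a group. Of 50 tested members 42 fell and none rose, and 46 fell when adjusted over the list alone, with a median log2 fold change of -0.75 (camera adjusted p 2.85e-23). Next to OAS2 and MX2 these included ISG15 (-0.99 ± 0.23), HLA-A (-0.80 ± 0.17), MX1 (-0.62 ± 0.10) and STAT1 (-0.57 ± 0.10), examples that were chosen after their values were seen. The 8 members that did not pass were IFI6 (0.17), BST2, TRIM21, UBE2L6, IFI27, HLA-E, HLA-F and IRF9. Of 13 tested genes of NF-kB and inflammation 4 fell and none rose, and 9 fell and 1 rose when adjusted over the list alone. Among them were RELB, an NF-kB subunit (-1.50 ± 0.12), and TNFAIP2 (-0.64 ± 0.11). The median of that list was -0.47 (camera adjusted p 0.00441, and adjusted p = 0.114 with an estimated correlation). Reads of HLA genes can be shared between near-identical copies, so their values are uncertain.

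Target genes of p53 rose. Of 33 tested, 27 rose and 1 fell, and 28 rose and 2 fell when adjusted over the list alone, with a median of 0.79 (camera adjusted p 1.10e-15). Besides TNFRSF10C and FDXR, these were for example TP53I3 (1.46 ± 0.11), GADD45A (1.09 ± 0.08) and BAX, an effector of apoptosis (1.04 ± 0.12). The member that fell was PMAIP1, which encodes the BH3-only protein NOXA (-0.82 ± 0.13). CDKN1A, the p21 gene, stood at 0.24 ± 0.09 (adjusted p 0.0822) and MDM2, which encodes the p53 ubiquitin ligase, at -0.34 ± 0.13 (adjusted p 0.0974), and both were picked out after their values were seen. Of 17 genes described in the literature as repressed by CtBP 7 rose and 3 fell, and 9 rose and 3 fell when adjusted over the list alone, with a median of 0.25 (camera adjusted p 0.0566). PERP (1.06 ± 0.07) and BAX rose most, and DSP (-0.84 ± 0.17) and PMAIP1 fell most.

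Cell cycle genes fell. Of 44 genes of the G1/S transition and DNA replication 25 fell and none rose, and 32 fell when adjusted over the list alone, with a median of -0.39 (camera adjusted p 5.73e-12). MCM2, a subunit of the replicative helicase, fell by 1.24 ± 0.09 on the log2 scale and RRM1, a subunit of ribonucleotide reductase, by 1.01 ± 0.08 (values -1.24 and -1.01), the latter with the 3′ UTR word GAGAAGT described further on. Of 42 genes of G2/M and mitosis 20 fell and none rose, and 26 fell when adjusted over the list alone, with a median of -0.36 (camera adjusted p 2.02e-09, and adjusted p = 0.114 with an estimated correlation). The kinetochore gene NUF2 (-1.19 ± 0.07) and the proliferation marker gene MKI67 (-0.84 ± 0.13) were among them. Of 37 genes of homologous recombination and the Fanconi pathway 19 fell and 1 rose, and 21 fell and 1 rose when adjusted over the list alone, with a median of -0.38 (camera adjusted p 2.51e-07, and adjusted p = 0.216 with an estimated correlation). RBBP8, which encodes the end resection factor CtIP, fell among these (-0.84 ± 0.06), and RAD51C rose (0.35 ± 0.09). RAD51C did not pass without CtBP1/2 siRNA replicate 1, 2 or 3 (adjusted p 0.0693, 0.0584 and 0.086) or control replicate 1, 2 or 3 (0.0528, 0.075 and 0.0823).

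Of 15 tested partners of CtBP 3 fell and none rose, the same numbers when adjusted over the list alone, with a median of -0.27 (camera adjusted p 0.00441, and adjusted p = 0.265 with an estimated correlation). HDAC1 fell most (-0.97 ± 0.07). Of 16 genes of the TRIM28 and HUSH silencing complexes 9 fell and none rose, and 10 fell when adjusted over the list alone, with a median of -0.33 (camera adjusted p 6.15e-04, and adjusted p = 0.452 with an estimated correlation). These included the histone methyltransferase gene SETDB1 (-1.15 ± 0.12).

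Further lists rose in the camera test, with smaller medians. Of 31 autophagy and lysosome genes 13 rose and 1 fell, and 14 rose and 1 fell when adjusted over the list alone, among them CTSL (1.36 ± 0.10) and GABARAPL1 (1.20 ± 0.14), with a median of 0.23 (camera adjusted p 8.81e-05, and adjusted p = 0.338 with an estimated correlation). Of 44 epithelial junction and polarity genes 12 rose and 4 fell, and 15 rose and 4 fell when adjusted over the list alone, with a median of 0.10 (camera adjusted p 0.0155, and adjusted p = 0.209 with an estimated correlation). PERP and the tight junction gene CLDN1 (0.84 ± 0.06) rose, while DSP and CLDN12 (-0.83 ± 0.09, a gene with the word GAGAAGT) fell. Of 45 nuclear genes for oxidative phosphorylation subunits 9 rose and none fell, and 8 rose when adjusted over the list alone, with NDUFA8 first (0.89 ± 0.14) and a median of 0.20 (camera adjusted p 7.43e-04, and adjusted p = 0.728 with an estimated correlation). Of 72 ribosomal protein genes 5 rose and 2 fell, while 1 fell when adjusted over the list alone, with a median of 0.21 (camera adjusted p 0.00173, and adjusted p = 0.754 with an estimated correlation). RPSA fell (-1.34 ± 0.18), with the reservation that its reads can be shared with pseudogenes. Among the 34 lists tested, 12 passed with the preset correlation, and those of interferon-stimulated genes, p53 targets and G1/S genes passed with an estimated correlation as well (adjusted p 0.00534, 0.00534 and 0.00513).

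Markers of other cell types stood near the detection limit for the most part. ACTA2, the smooth muscle actin gene that is shared by the mesenchymal and stromal lists, rose from 0.192 to 2.41 FPKM (2.07 ± 0.13). It was the only called gene among 4 tested stromal markers. Of 4 tested immune markers CD8A rose (0.54 ± 0.09) and CD74 and HLA-DRA (from 5.10 ± 0.236 to 2.32 ± 0.329 FPKM) fell. Of the endothelial and adipocyte markers 0 passed the expression filter.

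Among genes that fell, 408 of the 1666 with an annotated 3′ UTR (24.5%) carried the 7-base word GAGAAGT in their longest annotated 3′ UTR, against 13.6% of all 11311 genes searched and 8.07% of those that rose. Of the 10 named genes with the largest falls, GBP4 carried it. The word was chosen for its low z in these same fold changes, so part of its excess follows from the choice. Without the genes that carried this word or either of 2 words found with TRIM28 siRNA, 2246 of 10374 genes were called, 1208 higher and 1038 lower. With each library rescaled to the same FPKM sum, 40.3% of the called genes were higher (1349 against 2002 lower) in place of 48.8%. The number called was 2124, 2148 or 2171 without CtBP1/2 siRNA replicate 1, 2 or 3, 2180 or 2181 without control replicate 2 or 3, and 6870 without TRIM28 siRNA replicate 2, which shares the estimate of the spread. Of the 129 named genes called, 105 stayed called without each library in turn, and the highest number lost was 20, without CtBP1/2 siRNA replicate 3 or control replicate 3.

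**Figure D3:**
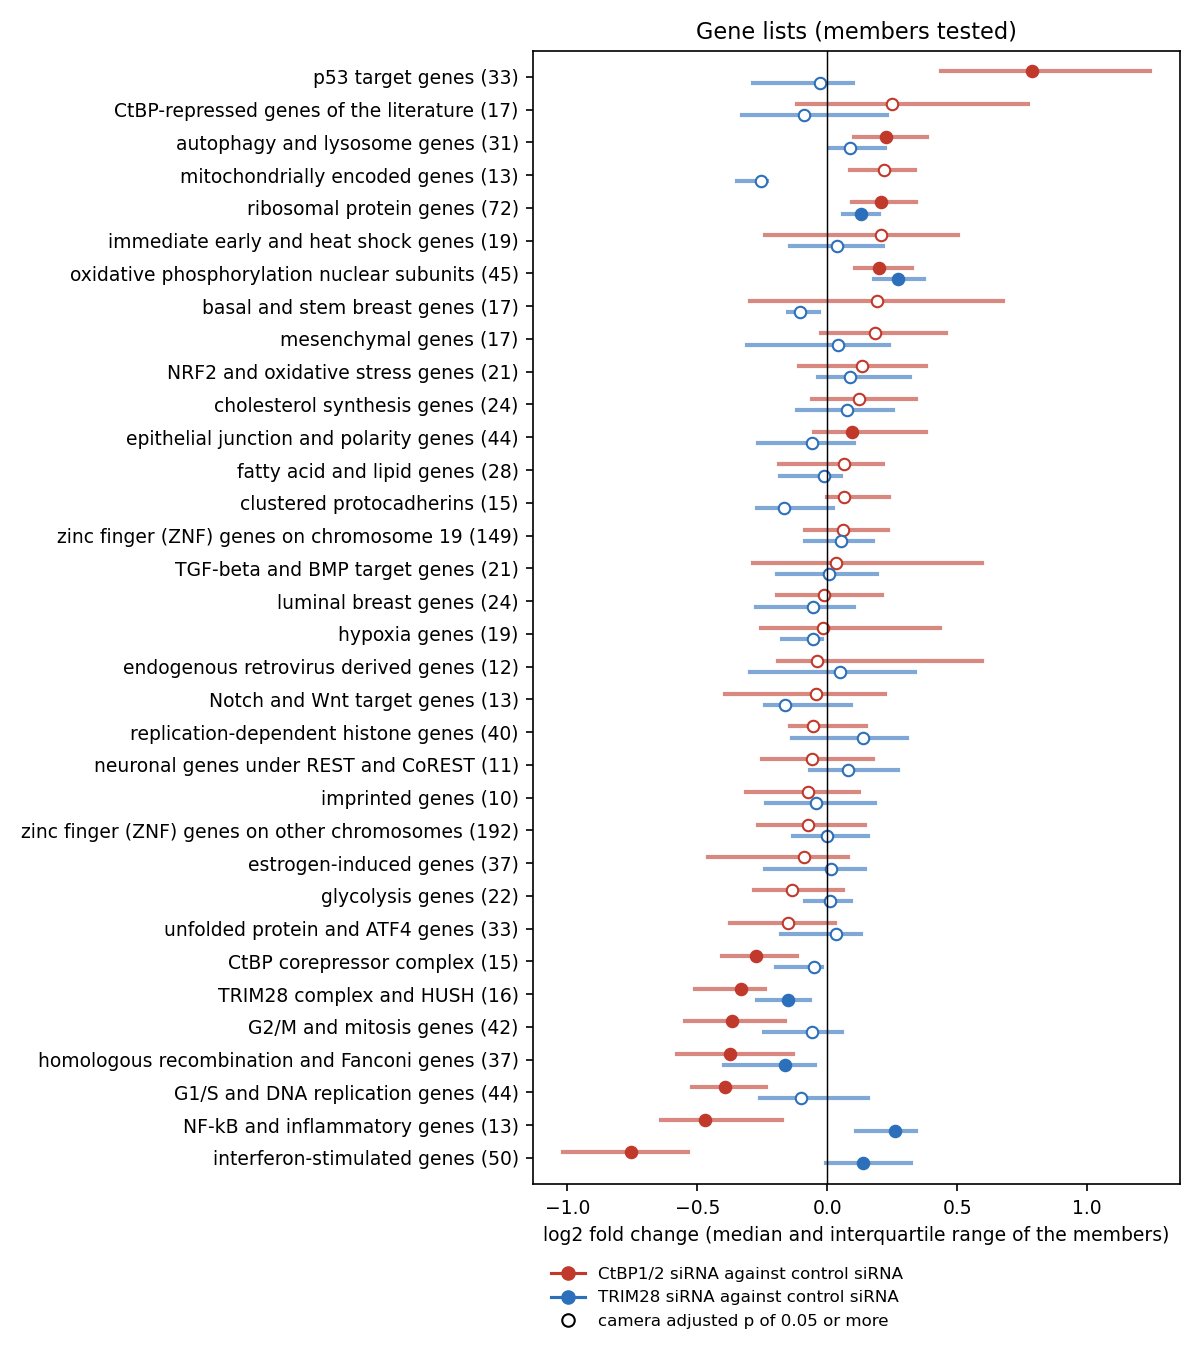
Median log2 fold change against control siRNA (points) and interquartile range over the tested members (lines) of 34 gene lists, for CtBP1/2 siRNA in red and TRIM28 siRNA in blue, with filled points where the camera adjusted p was under 0.05 at the preset correlation. Target genes of p53 lie highest with CtBP1/2 siRNA, at a median of 0.79, and interferon-stimulated genes lowest, at -0.75, while the medians with TRIM28 siRNA lie between -0.25 and 0.27.

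The comparison of TRIM28 siRNA with control siRNA asks which transcripts change when TRIM28 is lowered. SENP5, a protease of the SUMO pathway, fell from 13.7 ± 0.67 to 4.15 ± 0.309 FPKM (-1.61 ± 0.08), and CTNNA1, which encodes alpha-catenin of adherens junctions, from 60.9 ± 0.766 to 24.0 ± 1.49 FPKM (-1.33 ± 0.06). The MHC class II genes CD74 and HLA-DRA rose, CD74 from 11.9 ± 0.521 to 26.3 ± 5.33 FPKM (1.10 ± 0.13) and HLA-DRA from 5.10 ± 0.236 to 11.5 ± 1.41 FPKM (1.09 ± 0.11). MT1X, a metallothionein gene, rose from 1.73 ± 0.328 to 4.92 ± 1.66 FPKM (1.25 ± 0.21). ZNF138, a zinc finger gene, rose from 6.02 ± 0.602 to 12.1 ± 0.624 FPKM (0.95 ± 0.08).

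Of the 14074 genes tested 691 (4.91%) changed, 314 higher and 377 lower, and 58 of them differed by at least 2-fold, 19 higher and 39 lower. Further large rises were those of EMC6 (1.15), the chemokine gene CCL2 (1.04), OGFR (1.03) and the peroxiredoxin gene PRDX4 (1.01). Besides TRIM28 (-1.95), SENP5 and CTNNA1, the largest falls were those of CTDSP2 (-1.47), ARL5B (-1.22), HIPK3 (-1.20), the microRNA-processing enzyme gene DICER1 (-1.20), the thiamine transporter gene SLC19A2 (-1.19), MTPN (-1.14) and ZNF280C (-1.12). The 7 genes from CTDSP2 to ZNF280C each carried the word GTTCATG or the word TTGTGCT in the longest annotated 3′ UTR, while CTNNA1 carried neither and SENP5 carried GAGAAGT. Among all genes that fell and had an annotated 3′ UTR, 231 of 335 (69.0%) carried either word, against 24.5% of all genes searched and 11.2% of those that rose. Both words were chosen for their low z in these same fold changes, so part of that excess follows from the choice.

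Few members of the fixed lists passed the test. Of 149 tested zinc finger (ZNF) genes on chromosome 19, where KRAB zinc finger genes cluster, ZNF616 (0.76 ± 0.13) and ZNF544 (0.38 ± 0.08) rose and none fell, with a median of 0.05 (camera adjusted p 0.186), and 1 rose when adjusted over the list alone. Of 192 ZNF genes on other chromosomes 6 rose and 4 fell (8 and 5 when adjusted over the list alone), with a camera adjusted p of 0.657. ZNF616 did not pass without control replicate 1, 2 or 3 (adjusted p 0.0666, 0.0654 and 0.0703), and ZNF544 did not without these (0.122, 0.11 and 0.136), CtBP1/2 siRNA replicate 1, 2 or 3 (0.062, 0.0719 and 0.0757) or TRIM28 siRNA replicate 3 (0.068). Of 12 genes derived from endogenous retroviruses none was called, and 2 rose and 1 fell when adjusted over the list alone (camera adjusted p 0.657). The deposited values cover annotated genes only, so transcripts of retroviral repeats outside such genes were not measured. None of 10 imprinted genes was called, and 2 rose and 2 fell when adjusted over the list alone (camera adjusted p 0.83). None of 15 clustered protocadherin genes was called in either count (camera adjusted p 0.21), a result with little reach at their median level of 1.06 FPKM. Limma found 3518 genes in this comparison at an unadjusted p under 0.05. Of 4 tested immune markers CD74 and HLA-DRA rose.

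In the camera test 6 lists passed with the preset correlation and 0 with an estimated one. Nuclear genes for oxidative phosphorylation had a median of 0.27 (adjusted p 3.77e-07, and adjusted p = 0.791 with an estimated correlation), with 3 of 45 called, all higher, among them NDUFS2 (0.68 ± 0.11). In TRIM28 siRNA replicate 2 these genes stood higher by a median of 0.55, and without that library the median was 0.11 (adjusted p 0.00377). Genes of NF-kB and inflammation had a median of 0.26 (adjusted p 0.0175, and adjusted p = 0.58 with an estimated correlation), with CCL2 and NFKB2 (0.31 ± 0.07) higher among 13. Interferon-stimulated genes had a median of 0.14 (adjusted p 0.0251, and adjusted p = 0.58 with an estimated correlation), with TAP1 higher (0.30 ± 0.06) and DTX3L (-0.82 ± 0.10) and STAT2 (-0.33 ± 0.08) lower among 50. Genes of homologous recombination and the Fanconi pathway had a median of -0.16 (adjusted p 0.00657, and adjusted p = 0.614 with an estimated correlation), with FANCF higher and FANCA lower. Of these 37 genes 28 were lower in TRIM28 siRNA replicate 2 than in the mean of replicates 1 and 3, and without that library the median was -0.12 (adjusted p 0.0119). Genes of the TRIM28 and HUSH complexes had a median of -0.15 (adjusted p 0.0175, and adjusted p = 0.783 with an estimated correlation), with CBX5 alone called (-0.60 ± 0.07). The ribosomal protein list had a median of 0.13 (adjusted p 0.0475, and adjusted p = 0.839 with an estimated correlation) with 0 of 72 genes called, and its direction turned to a median of -0.11 (adjusted p 2.52e-05) without TRIM28 siRNA replicate 2, in which those genes were higher. The NF-kB list did not pass without TRIM28 siRNA replicate 3 (0.085), nor the interferon list without TRIM28 siRNA replicate 3 (0.121) or control replicate 2 (0.0575), nor that of the TRIM28 complexes without TRIM28 siRNA replicate 2 (0.104). The ribosomal list did not pass without CtBP1/2 siRNA replicate 1, 2 or 3 (0.0537, 0.0539 and 0.0556) or control replicate 2 or 3 (0.168 and 0.0656). Among the members named, DTX3L and CBX5 stayed called without each library in turn, while TAP1, STAT2, NFKB2, CCL2, NDUFS2, FANCF and FANCA did not pass without, among others, control replicate 2 (adjusted p from 0.0502 to 0.177). When adjusted over the list alone, 5 genes rose and none fell for oxidative phosphorylation, 2 rose and none fell for NF-kB, 5 rose and 3 fell for interferon, 1 rose and 3 fell for recombination, 1 fell for the TRIM28 complexes and none was called for ribosomal proteins.

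Of 33 p53 targets TP53I3 (0.48) and GADD45A (0.37) rose and TP53INP1 (-0.74) and PLK2 (-0.30) fell, and 2 rose and 5 fell when adjusted over the list alone (camera adjusted p 0.48). Among 44 G1/S genes 3 fell, MCM5 (-0.40) and MCM2 (-0.36) among them, and 1 rose and 4 fell when adjusted over the list alone (0.17). These p53 and G1/S genes did not pass without, among others, control replicate 2 (adjusted p from 0.109 to 0.154). In other lists HMGCR, the rate-limiting enzyme gene of cholesterol synthesis, fell (-1.03 ± 0.11), as did the cytokinesis gene ANLN (-1.01 ± 0.18), the amino acid transporter gene SLC7A5 (-0.60 ± 0.08) and the thioredoxin reductase gene TXNRD1 (-0.77 ± 0.13). HMGCR, ANLN, SLC7A5, CBX5 and DTX3L carried GTTCATG in the 3′ UTR, TP53INP1, MCM5 and MCM2 carried TTGTGCT, and TXNRD1 and PLK2 carried neither word. ANLN (adjusted p 0.0816, 0.0742 and 0.0796) and TXNRD1 (0.0809, 0.0724 and 0.0736) did not pass without control replicate 1, 2 or 3.

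Without TRIM28 siRNA replicate 2 the count of called genes was 1833, 838 higher and 995 lower, and 681 of the 691 were among them. Interferon-stimulated genes then had 12 higher and 4 lower (camera adjusted p 0.00874) and ZNF genes on chromosome 19 had 17 higher and 3 lower (0.00874), both with the preset correlation. With all libraries these lists had an adjusted p = 0.58 and an adjusted p = 0.791 with an estimated correlation. With only the 2 groups compared the count was 23, 3 higher and 20 lower, and with library quality weights 3469, 1777 higher and 1692 lower. It was 278, 293 or 296 without CtBP1/2 siRNA replicate 1, 2 or 3, 131, 122 or 117 without control replicate 1, 2 or 3, and 204 of 10374 without genes that carried a word, 135 higher and 69 lower. With libraries rescaled to the same FPKM sum, 55.9% of the called genes were higher (292 against 230 lower) in place of 45.4%. Of the 86 named genes called, 10 stayed called under each alternative that tested them, namely TRIM28, SENP5, CTNNA1, CTDSP2, SLC19A2, DKK1, C5orf22, HLA-DRA, TPM4 and ZNF138. Of these SENP5, CTDSP2, SLC19A2 and C5orf22 carried a word and were not tested in the alternative without such genes. Calls were lost for 56, 61 or 61 of them without control replicate 1, 2 or 3, for 37, 37 or 35 without CtBP1/2 siRNA replicate 1, 2 or 3, and for 12, 1 or 24 without TRIM28 siRNA replicate 1, 2 or 3. PRDX4, HIPK3, DICER1, MTPN and ZNF280C did not pass without control replicate 1, 2 or 3 (adjusted p from 0.0531 to 0.0817), nor MT1X, EMC6 and CCL2 without control replicate 2 or 3 (0.0502 to 0.0703).

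The direct comparison of the knockdowns asks where their effects differ, and it does not use the control libraries except for the spread. TGFB2 was higher with CtBP1/2 siRNA than with TRIM28 siRNA by 2.93 ± 0.17 on the log2 scale, and CDKN2B (2.27), TRIM28 itself (2.12) and TNFRSF10C (2.05) were higher as well. CD74 was lower by -2.95 ± 0.13, followed by RTP4 (-2.45), SLC15A3 (-2.10), the type III interferon gene IFNL1 (-2.09) and HLA-DRA (-2.08). Of the 50 interferon-stimulated genes 42 were lower and none higher, with a median of -0.80 (camera adjusted p 4.36e-25). Of the 33 p53 targets 27 were higher and 1 lower, with a median of 0.86 (1.01e-16), and of the 44 G1/S genes 23 were lower and none higher, with a median of -0.35 (2.13e-08). Genes of NF-kB and inflammation were lower in 9 of 13 cases, with a median of -0.63 (7.38e-05), and these 4 lists also passed with an estimated correlation. When adjusted over the list alone, 43 interferon-stimulated genes, 25 G1/S genes and 9 NF-kB genes were lower, and 27 p53 targets were higher and 1 lower. CtBP-repressed genes (8 higher and 1 lower of 17, camera adjusted p 0.00632, and adjusted p = 0.105 with an estimated correlation) and epithelial junction genes (15 and 3 of 44, 8.44e-04, and adjusted p = 0.0728 with an estimated correlation) were among 8 further lists that passed with the preset correlation.

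In the comparison of the knockdowns 3738 of 14074 genes differed, 1753 higher and 1985 lower with CtBP1/2 siRNA, and each of the 15 named genes that were called, TGFB2 and CD74 among them, stayed called without each library in turn. The count was 2362, 2415 or 2447 without CtBP1/2 siRNA replicate 1, 2 or 3, 6190 without TRIM28 siRNA replicate 2, and 2274 of 10374 without genes that carried a word. With libraries rescaled to the same FPKM sum 38.4% of the called genes were higher in place of 46.9%.

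Genes called in both knockdowns against control moved in the same direction in 259 cases and in opposite directions in 77. Higher in both were 147 genes, among them the tropomyosin gene TPM4 (1.38 ± 0.06 with CtBP1/2 siRNA and 0.89 ± 0.06 with TRIM28 siRNA), EMC6 (1.01 and 1.15) and ZNF138 (0.80 and 0.95). Lower in both were 112, among them DTX3L (-0.87 and -0.82), the glucosylceramide synthase gene UGCG (-0.89 and -0.76), C5orf22 (-0.68 and -0.91) and ANP32E (-0.65 and -0.76). Of 102 genes lower in both with an annotated 3′ UTR, 21 (20.6%) carried a word of each siRNA, against 5.39% of all genes searched and 4 of 128 genes higher in both (3.13%). UGCG and C5orf22 did so. The words were chosen from the same fold changes, so this excess is not independent of that choice. TGFB2 (1.94 and -0.99), the p53-induced gene TP53INP1 (0.98 and -0.74) and the Wnt antagonist gene DKK1 (0.91 and -0.73) rose with CtBP1/2 siRNA and fell with TRIM28 siRNA, and of these TGFB2 and TP53INP1 carried TTGTGCT. CD74 (-1.85 and 1.10), HLA-DRA (2.32 and 11.5 FPKM against 5.10 FPKM in control) and IFNL1 (-1.18 and 0.91) did the reverse. The calls with TRIM28 siRNA were lost for TGFB2 without control replicate 1, 2 or 3 (adjusted p 0.0691, 0.0785 and 0.0703), for EMC6 without control replicate 2 or 3 (0.0528 and 0.0531) and for IFNL1 without control replicate 3 (0.0521). TP53INP1 lost it without control replicate 1, 2 or 3 (0.113, 0.118 and 0.0796) and without CtBP1/2 siRNA replicate 1, 2 or 3 (0.0639, 0.0634 and 0.0644).

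Independent lists of these lengths would share 86.1 genes in the same direction, 38.1 higher and 48.0 lower, and 85.7 in opposite directions. Across genes, which are not independent replicates, the covariance of the fold changes was 0.0392 against 0.0155 in 100 simulations of unchanged groups against the same controls, a difference of 0.0237. The correlation was below its simulated value (0.323 against 0.498), as was the share of genes with the same sign (61.3% against 66.6%). The shared controls alone set those simulated values, and effects particular to either knockdown lower both. Neither value can therefore show whether effects were shared or opposed. The 3 control libraries are too few to be split, so part of the overlap in the same direction may come from the shared controls. The count in the same direction was 92, 95 or 98 without CtBP1/2 siRNA replicate 1, 2 or 3, 53, 46 or 44 without control replicate 1, 2 or 3, 902 without TRIM28 siRNA replicate 2 and 96 without genes that carried a word. In opposite directions the corresponding counts were 26, 28, 26, 17, 15, 13, 361 and 27. With only the 2 groups compared in each fit, 10 genes were called in the same direction and 9 in opposite directions.

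**Figure D4:**
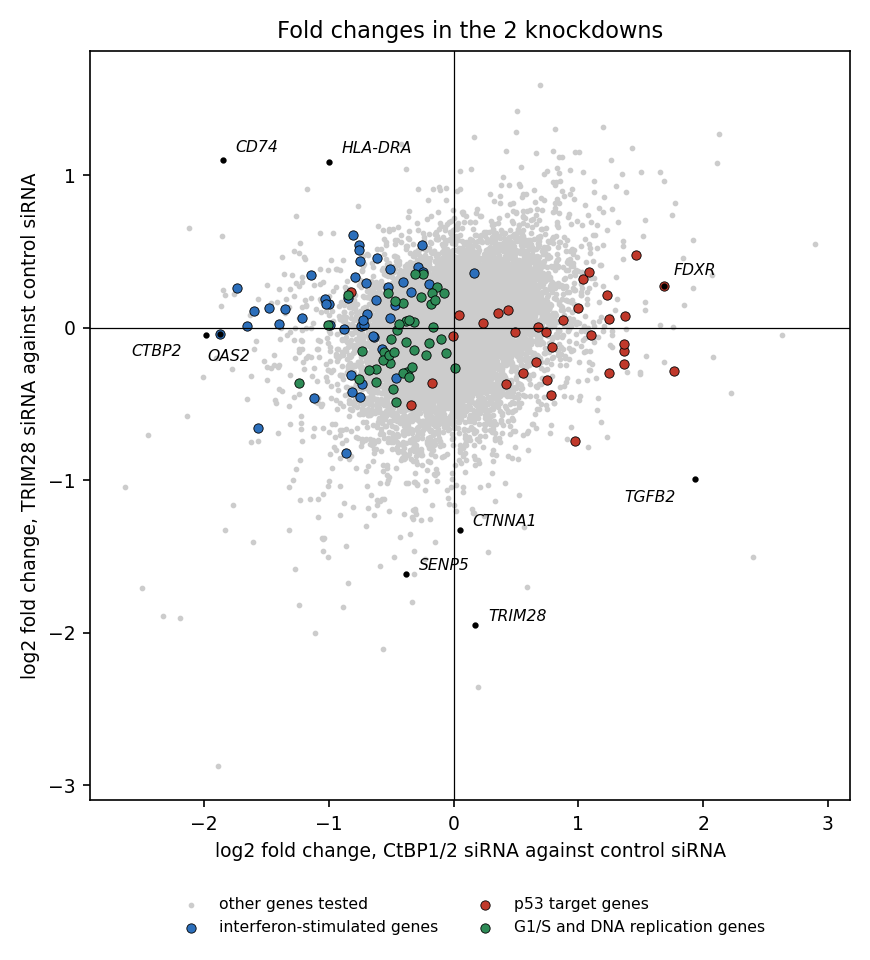
Log2 fold change of each of 14074 genes with TRIM28 siRNA (vertical axis) against that with CtBP1/2 siRNA (horizontal axis), both relative to the same control siRNA libraries, with members of 3 gene lists in colour. Interferon-stimulated genes lie to the left, with a median of -0.75, p53 target genes to the right, with a median of 0.79, and both lists lie near 0 on the vertical axis, with medians of 0.14 and -0.03.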

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

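The alternatives with a GC and length trend removed and without genes holding a 3′ UTR word were chosen after the data were seen. No named gene that was called reversed under any alternative run. Of the named genes called, 92 of 129 with CtBP1/2 siRNA, 10 of 86 with TRIM28 siRNA and 14 of 15 in the comparison of the knockdowns kept their call under each alternative that tested them, which for genes holding a word leaves out the alternative without such genes, and of the lists 3 of 12 and 0 of 6 did. With an estimated correlation 3 lists passed with CtBP1/2 siRNA and 0 with TRIM28 siRNA. The ribosomal protein list with TRIM28 siRNA reversed to lower with library quality weights (adjusted p 0.00501) and without TRIM28 siRNA replicate 2 (2.52e-05), and left-out libraries otherwise took its adjusted p to 0.168 at most. For CtBP1/2 siRNA against control, 3498 genes became 7334 with library quality weights, 6908 with only the 2 groups compared, 1308 at 1.5-fold or more and 2246 without genes holding a word, and 2124 to 6870 with 1 library left out. For CtBP1/2 against TRIM28 siRNA, 3738 became 7910, 2457, 1503 and 2274 in the same order, and 2362 to 6190 with 1 library left out. For TRIM28 siRNA against control, 691 became 352 without a filter on low values, 3469 with weights, 23 with only the 2 groups compared, 284 at 1.5-fold or more and 204 without genes holding a word, and 117 to 1833 with 1 library left out. Genes changed in both knockdowns in the same direction were 153 without a filter, 390 with quantile normalization, 1549 with weights, 10 with only the 2 groups compared, 54 at 1.5-fold or more and 96 without genes holding a word, and 44 to 902 with 1 library left out. In opposite directions they were 36, 122, 649, 9, 16 and 27 in the same order, 142 with the GC and length trend removed, and 13 to 361 with 1 library left out. With the fold minimum and without genes holding a word fewer genes can pass. With only the 2 groups compared, the remaining group no longer enters the spread, and the TRIM28 siRNA libraries deviated most from their group mean. For the other alternatives the cause was not tested.

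Same-numbered libraries did not deviate together, with correlations from -0.153 to 0.0683, and 2 of 9 libraries correlated best with libraries of their own number. With the replicate block, 241 genes were called with TRIM28 siRNA, 91 in both knockdowns in the same direction and 25 in opposite directions. The block moved no other count of calls by more than 1.5 times. Depth limits genes near 0.5 FPKM, where the filter and pseudocount act, and the median standard error of 0.125 limits small changes.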

Other observations

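The tests of interferon ligands, of recovered reads, of a wrong label and of the siRNA sites in the target transcripts were chosen after the result was seen, as were the alternatives without a GC and length trend and without genes holding a 3′ UTR word.

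Genes of the luminal and estrogen-responsive program of MCF-7 cells moved in both directions with CtBP1/2 siRNA. Of 37 estrogen-induced genes 10 fell and 3 rose, the same numbers when adjusted over the list alone, with a median of -0.09 (camera adjusted p 0.0566). GREB1 (-0.86 ± 0.17) and the transcription factor gene EGR3 (-1.02 ± 0.14) fell, and the EGFR ligand gene AREG rose (0.60 ± 0.14), though AREG did not pass without CtBP1/2 siRNA replicate 1 or 3 (adjusted p 0.0575 and 0.0569) or control replicate 1 or 3 (0.0525 and 0.0585). Of 13 Notch and Wnt targets 4 fell and 1 rose (4 and 1 over the list alone, camera adjusted p 0.445), with MYC (-0.75 ± 0.06) and CCND1 (-0.76 ± 0.07) lower and DKK1 higher. Of 24 luminal genes 4 rose and 2 fell, 4 and 2 over the list alone, with a median of -0.01 against an upward camera direction (adjusted p 0.797). Of 17 basal and stem cell genes 8 rose and 2 fell, and 8 rose and 5 fell when adjusted over the list alone (camera adjusted p 0.0839), with ANXA1 (1.54 ± 0.15) and LAMB3 (0.94 ± 0.09) higher and SOX9 lower (-0.65 ± 0.14). Of 17 mesenchymal genes 6 rose and 2 fell, the same over the list alone (camera adjusted p 0.0566), with CCN2 higher (1.03 ± 0.15) and THBS1, a gene with the word GAGAAGT, lower (-0.90 ± 0.09).

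Of 21 TGF-beta and BMP targets 6 rose and 5 fell with CtBP1/2 siRNA (camera adjusted p 0.486), CDKN2B and TGFB2 first. None of the next 7 metabolic and stress lists passed the camera test, with 4 rising and 4 falling of 22 glycolysis genes (0.44), 5 and 3 of 24 cholesterol genes (0.226), 2 and 4 of 28 fatty acid genes (0.797, SREBF1 -0.90, with GAGAAGT), 3 and 7 of 33 unfolded protein and ATF4 genes (0.0638, CHAC1 -0.87), 5 and 5 of 19 hypoxia genes (0.756), 6 and 1 of 21 NRF2 genes (0.187, AKR1C3 1.12) and 6 and 5 of 19 immediate early and heat shock genes (0.44). Adjusted over the list alone, these counts were 6 and 6, 4 and 4, 5 and 3, 2 and 4, 3 and 9, 5 and 5, 7 and 1, and 10 and 5. Of 149 ZNF genes on chromosome 19, 12 rose, ZNF761 first (0.81), and 4 fell (0.162), and of 192 others 17 rose and 30 fell (0.295, ZNF131 -1.09), and over the list alone 5 and 2, and 17 and 32. Of 12 retrovirus-derived genes 5 rose, RTL8C first (1.12), and 2 fell (0.536), with a median of -0.04 and a mean of 0.17. Among 40 histone genes 1 rose and 6 fell (0.667), among 11 neuronal genes 1 each (0.798, VGF -1.23), among 10 imprinted genes INPP5F fell (0.756; not without CtBP1/2 siRNA or control replicate 3, adjusted p 0.0558 and 0.0521), and among 15 protocadherins (0.464) and 13 mitochondrially encoded genes (0.172) limma called 0. Of the cancer-testis genes only DDX43 passed the expression filter, and it was not called.

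With TRIM28 siRNA the synaptic vesicle gene SYP rose (0.60 ± 0.09), as did VGF (0.55 ± 0.13), among 11 neuronal genes (2 rose, 3 over the list alone, camera adjusted p 0.173). The immediate early genes IER2 (0.66 ± 0.10) and IER3 (0.62 ± 0.13) rose among 19 (3 rose, 0.755). SGK3 (-0.74 ± 0.10), with the word GTTCATG, fell among 37 estrogen-induced genes (1 rose and 3 fell, 0.657), and BMF (-0.69 ± 0.09), a BH3-only gene without either word, fell among 17 CtBP-repressed genes (1 rose and 1 fell, 0.321). HDAC1 (0.62 ± 0.07) and BCL3 (0.33 ± 0.08) rose among 15 CtBP partners (0.657), and both fell with CtBP1/2 siRNA. BCL3 did not pass with TRIM28 siRNA without CtBP1/2 siRNA replicate 1, 2 or 3, TRIM28 siRNA replicate 3 or control replicate 1, 2 or 3 (adjusted p from 0.0858 to 0.18), nor with CtBP1/2 siRNA without replicate 3 of that group or of the control (0.0508 and 0.0535). Without control replicate 2 or 3 SYP (0.0525 and 0.0543) did not pass, nor did IER2 without control replicate 1, 2 or 3 (0.0566 to 0.0673). VGF and IER3 did not pass without any 1 of the control or CtBP1/2 siRNA replicates or TRIM28 siRNA replicate 3 (0.0592 to 0.172).

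With CtBP1/2 siRNA, genes with GAGAAGT in the 3′ UTR stood lower than others with a z of -13.13 (lowest of 100 permutations -4.94), by -0.129 ± 0.002 (SD, n = 3), and with TRIM28 siRNA genes with GTTCATG did so with a z of -11.84 (lowest of permutations -4.68), by -0.083 ± 0.010. These SDs are over the knockdown libraries, each taken against the same mean of the controls, so they leave out the spread of the controls. A candidate explanation, tested with these values, is silencing of unintended transcripts through the siRNA seed. Of 21 stretches of 19 bases shared by CTBP1 and CTBP2, 1 ends in GAGAAGT and 1 more base (chromosome 4, 1228273 to 1228291, exon 3 of 9, and chromosome 10, 125003034 to 125003052, exon 3 of 9), where 0.132% of words would, and in TRIM28 1 stretch (chromosome 19, 58547428 to 58547446, exon 4 of 17) pairs GTTCATG and the second word, TTGTGCT, as the strands of 1 duplex would, the only such gene of 11311. These places may be the siRNA sites, but the sequences are not given, and genes that lost the target protein's control could carry the word too. Word genes in the fall may hence not depend on CtBP or TRIM28, while 2246 and 204 genes were called without them. Only genes with exact matches of the words in the longest 3′ UTR were left out. Overlapping words with strong shifts, such as AGAAGTA with CtBP1/2 siRNA (z of -9.301) and TTCATGA with TRIM28 siRNA (-7.223), were kept. The remaining calls are therefore not shown to be free of seed effects.

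The fall of interferon-stimulated genes with CtBP1/2 siRNA kept a median of -0.77 (value -0.7702) with a GC and length trend removed, which argues against that trend as the cause. The 44 members without GAGAAGT had a median of -0.74 (value -0.7386), and 36 of them fell, which argues against direct silencing through that word. All 4 tested interferon ligand genes fell, IFNB1 (-1.26 ± 0.21, 6 to 15 reads against 29 to 50), IFNL1 (-1.18 ± 0.13), IFNL2 (-1.07 ± 0.23) and IFNL3 (-1.36 ± 0.26), the last 2 near-identical paralogs whose reads can be shared, which is consistent with less interferon made than in the control cultures. Whether that came from the loss of CtBP, from a silenced regulator or from a weaker response to this siRNA than to the control siRNA stays open, since no untransfected cells were measured. With TRIM28 siRNA IFNL1 rose (0.91 ± 0.13), and IFNB1 stood at 0.73 (adjusted p 0.0878).

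TRIM28 siRNA replicate 2 differed from replicates 1 and 3 with a ratio of chi-square to degrees of freedom of 76.1 and 62.3, against 2.04 to 7.05 for other pairs within groups. Its 18286340 recovered reads, against 16683150 in the lowest library, argue against low depth, and its TRIM28 level of 23.08 FPKM, against 75.2 in the lowest library of the other groups, against a library of another group. The SD of its deviations fell from 0.324 to 0.29 (value 0.2895) with a GC and length trend removed and stayed above the 0.168 of the highest library of the other groups, so that trend may account for a part only. Higher ribosomal protein and lower mitochondrially encoded transcripts could come from the culture or from the RNA preparation, and no biological explanation was tested.

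The 6 libraries of each comparison can be split in 10 ways, too few for a share under 0.05. The real split gave the highest count in each (1 of 10), with 3498 genes against 1 in the highest other split for CtBP1/2 siRNA, 691 against 2 for TRIM28 siRNA and 3738 against 1 between the knockdowns. In the other splits the real group difference enters the spread and lowers the counts, so these counts do not measure a level of random calls. Among words of genes that stood higher, CGGAGAA had a z of 5.60 with TRIM28 siRNA (highest of 100 permutations 4.53). The highest word with CtBP1/2 siRNA was TCGGAGA, with a z of 4.32 (highest of permutations 5.19). With TRIM28 siRNA, words down to rank 10 on that side (GAGATTG, z of 4.71) lay above the highest permutation. A z past the permutations is therefore not by itself particular to an siRNA seed.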
